A study of Caenorhabditis elegans with 12 samples.

How the data were processed

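The series holds 12 small RNA libraries of whole Caenorhabditis elegans, 1 file of aligned reads for each. Embryos were placed on bacteria that express dsRNA against oma-1 and grown for about 48 h to the L4 stage, per the labels' protocols, which give this for P0 and F1 alike. RNA of about 18 to 35 nt was taken from a gel with 20 ug of total RNA, ligated to a 3′ linker and, after treatment of the 5′ ends with phosphatase and kinase, to a 5′ linker with 1 of 2 barcodes, per the labels' protocols. This treatment makes RNAs with a 5′ triphosphate, such as siRNAs copied from mRNA, ligatable. The barcode followed the generation, per the labels. Reads were aligned with Bowtie, per the submitters' processing notes; its version and settings, the genome build and any filters on reads are not given in the sources used here. The deposited files hold, as the authors left them, 1 line per read with chromosome, start, end, read name, a score and the strand. The score in the deposited files is 255 on every line and says nothing about how many places a read matched. Reads of near-identical genes are therefore uncertain, since nothing shows how the alignment placed them.

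No column of the deposited files is a count, so reads per gene were counted from the lines. In WT F1 replicate 1 every line was present 2 times (671440 lines, 335720 reads), and each read was counted 1 time. Within each library all read names came from 1 sequencer run, and whether libraries shared a run was not compared. Genes came from Ensembl release 115 of the WBcel235 annotation: 22113 genes, of which 19985 protein-coding genes and 2128 pseudogenes. The exons of this annotation matched the reads best when read places were moved by -6 to 101 nt, depending on the window of 2 Mb, and by 13 nt in the window of oma-1. The files thus use another build than WBcel235, assignment to genes is approximate, and positions are printed only as the files give them. A read of 20 to 24 nt counted for a gene if its 5′ end lay in an exon on the opposite strand, with the places as deposited. Such reads are called antisense siRNAs. Reads in exons of more than 1 gene on that strand were left out. A read of any length whose 5′ end lay within 110 nt of a miRNA gene on its strand counted as miRNA, and otherwise near a gene of rRNA, tRNA, snRNA or snoRNA as structural RNA. Such reads were not taken out of the antisense counts. Hairpins nearer than 250 nt on a strand formed 1 entry, which gave 234 miRNA entries. Remaining reads that began on the strand of 1 of 15363 annotated 21U-RNA genes, at its annotated start or up to 40 nt before it in chromosome position, counted as 21U-RNA. Windows of the same size 120 to 160 nt away held 6.18% to 14.5% as many reads, and this background was not taken off.

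The design fixed before the data were examined named limma-voom for the case that no column holds counts, and this was used. Genes were kept with at least 10 reads at the median library size in at least 2 libraries and at least 15 reads in all, which left 2319. Libraries were scaled by TMM factors (trims of 30% and 5%). The model had 1 mean per group over the 12 libraries, and contrasts were taken within P0, within F1, over both generations (4 libraries against 4), between generations, and as the difference of the mutant effect between F1 and P0. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM are counts per 1000000 TMM-scaled antisense reads of the tested genes, and RPM are reads per 1000000 aligned reads. Gene list tests used limma's camera with a preset correlation of 0.01 and again with an estimated correlation, and limma's fry. The 17 lists, of which 15 had at least 3 tested genes and a test, were fixed before the data were examined: oogenesis and maternal genes, sperm genes, ERGO-1 targets, loci of WAGO or piRNA-directed siRNAs, small RNA pathway genes, germ granule genes, chromatin regulators, and histone, ribosomal protein, BATH, MATH and F-box, C-type lectin, nuclear hormone receptor, chemoreceptor, collagen, muscle, intestine and neuron genes, and a list of 18 miRNA markers. The same test was run on 97 miRNA entries (reads of 20 to 24 nt) and on 5 genes with antisense reads of 26 nt. Shares of read classes and the relative position of reads on transcripts (the median over genes with at least 50 reads in every library) were compared by exact two-sided permutation tests, where 4 libraries against 4 cannot go below 0.0286 and 2 against 2 not below 0.333.

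Named genes were chosen by a rule fixed before the data were examined. It always takes oma-1, oma-2, znfx-1 and wago-4. For each mutant over both generations it takes the 10 largest rises and the 10 largest falls among genes with a gene-class symbol that passed, had the same sign in P0 and F1, had no overlap between 4 mutant and 4 WT libraries, and had a mean of at least 10 CPM in either. From each list it takes the 2 largest changes in each direction, and from the interaction and generation contrasts oma-1 and the 3 largest in each direction. A gene without reads in a group was compared with a floor of 3 reads over the group. A gene with 1 to 3 reads is given as a ratio with an exact 95% interval of counting error.

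Depth limits the F1 results. Aligned reads per library were 510999 and 1277845 in WT P0, 504654 and 883547 in znfx-1 P0, 858027 and 829968 in wago-4 P0, 335720 and 152617 in WT F1, 268545 and 84952 in znfx-1 F1, and 260917 and 170404 in wago-4 F1. The tests were tested on simulated data with 200 of 2319 genes changed in znfx-1. They found 28% of 2-fold and 84% of 4-fold changes over both generations, 19% and 74% in P0, and 2% and 25% in F1, with 4, 4 and 1 unchanged genes called. These simulations used 1 common dispersion, which understates the spread between real libraries. Correlations of log2 CPM between libraries were 0.595 to 0.900 within groups and 0.276 to 0.806 between genotypes of 1 generation.

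Alternatives were 4 other scalings (median-ratio factors, and totals of non-structural, miRNA or 21U-RNA reads), no filter beyond 1 read, limma-trend with a prior count of 2, reads of all lengths, reads of 22 nt, blocks by replicate number, only the groups compared, moved read places, the doubled file as deposited, and each library left out in turn. The totals of non-structural, miRNA or 21U-RNA reads hold reads of every length. For oma-1 also only the reads more than 100 nt outside the block of sense reads were used. The common WT libraries of both mutant comparisons were examined with 50 simulations and by splitting them. Reads with a 5′ G were not analysed here, since no genome sequence was used. Versions were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.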

Results

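Small RNAs were sequenced from whole Caenorhabditis elegans at the L4 larval stage in an experiment with bacteria, fed to the worms, that express double-stranded RNA (dsRNA) against oma-1, a germline gene with a role in oocyte maturation. Animals of 3 genotypes were used: wild type (WT), mutants of znfx-1, a gene for a helicase of germ granules, and mutants of wago-4, a gene for a germline Argonaute protein. Each genotype was sampled in the generation called P0 and in the next, called F1, with 2 libraries per group and 12 libraries in all. The study's design text asks whether small RNAs directed by the fed dsRNA depend on these genes. The files listed 504654 to 1277845 aligned reads per library in P0 and 84952 to 335720 in F1. Reads shorter than 18 nt made up 9.38% to 20.2% of the P0 libraries and 30.5% to 70.2% of the F1 libraries. Reads of 20 to 24 nt antisense to exons, called antisense siRNAs here, numbered 7228 to 360439 per library. The lowest value of both counts was that of znfx-1 F1 replicate 2. The labels give the same feeding protocol for P0 and F1, but the 6 F1 libraries held 1 oma-1 sense read in all, against 344 to 776 in each P0 library, and whether F1 animals were fed is not given in the sources used here. Every P0 library carried another 5′ linker barcode than every F1 library, so generation and barcode cannot be told apart. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between libraries, which may be technical. Intervals and limits from read numbers cover counting error only.

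The mutated genes were examined in each library before the comparisons. Antisense siRNAs against znfx-1 stood at 326, 274, 201 and 117 counts per 1000000 (CPM, TMM-scaled) in the znfx-1 libraries and at 831 to 1159 CPM in the 4 WT libraries. They fell in the mutant by 2.04 on the log2 scale (SE 0.34, n = 4 against 4, limma-voom, adjusted p = 5.06e-07). Antisense siRNAs against wago-4 stood at 933 to 1214 CPM in the wago-4 libraries and at 1363 to 1816 CPM in WT. This difference did not pass (log2 fold change -0.49 ± 0.28, SE, limma-voom, adjusted p = 0.335). These reads are small RNAs made against the genes, not their mRNA, and the extent of each mutation is not given in the sources used here, so they do not check the genotype labels directly.

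In P0, antisense siRNAs against oma-1 stood at 1214 ± 150 reads per 1000000 aligned reads (RPM) in WT, 1213 ± 185 in znfx-1 and 841 ± 151 in wago-4 (SD, n = 2 each). In F1, WT animals had 921 ± 404 RPM, whereas znfx-1 mutants had 71.4 ± 67.6 and wago-4 mutants 98.4 ± 39.6 (SD, n = 2 each). The mutant levels were 7.75% and 10.7% of the WT mean. Relative to its own P0 mean, the F1 level was 75.9% in WT, 5.88% in znfx-1 and 11.7% in wago-4. The 4 mutant F1 libraries held 32, 2, 33 and 12 oma-1 antisense reads, against 405 and 97 in WT F1. The lowest of these, 2 reads in znfx-1 F1 replicate 2, gives 23.5 RPM with an exact Clopper-Pearson 95% interval of 2.85 to 85.0 RPM.

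**Figure D1:**
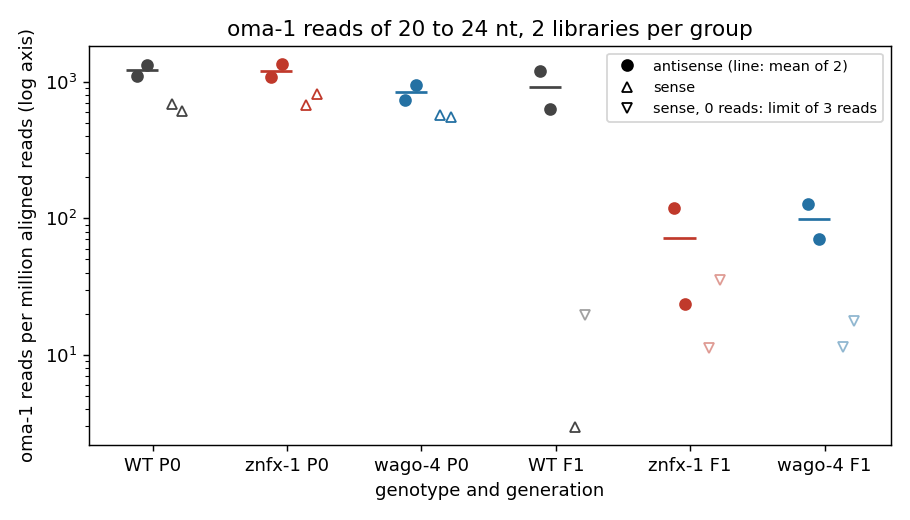
Reads of 20 to 24 nt in exons of oma-1 in RPM (log axis) in each of the 12 libraries, by genotype and generation. Filled circles are antisense reads with a line at the mean of 2 libraries, open upward triangles are sense reads, and faint downward triangles mark the limit of 3 reads where no sense read was found; the WT F1 mean is 921 and the mutant F1 means are 71.4 and 98.4.

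In F1, oma-1 siRNAs fell in both mutants compared with WT. The log2 fold change was -3.63 ± 0.48 in znfx-1 (SE, 12.3-fold lower, limma-voom, adjusted p = 2.33e-08) and -3.03 ± 0.42 in wago-4 (SE, 8.19-fold lower, adjusted p = 1.48e-07). In P0 neither mutant passed: the values were 0.26 ± 0.37 in znfx-1 (SE, limma-voom, adjusted p = 0.705) and -0.33 ± 0.37 in wago-4 (SE, adjusted p = 0.861). Most P0 antisense reads lay in the block of sense reads described below, so these values say little about reads outside it. From P0 to F1 the gene fell by 4.22 in znfx-1 (SE 0.48, limma-voom, adjusted p = 1.93e-10) and by 3.03 in wago-4 (SE 0.42, adjusted p = 2.84e-07). The WT value was -0.33 ± 0.38 (SE, limma-voom, adjusted p = 0.946). With miRNA totals as the scaling the falls of 4.22 and 3.03 became -3.12 and -2.49 and did not pass, and with totals of non-structural reads the value in wago-4, -3.04, did not (adjusted p over the 26 alternatives 2.03e-30 to 0.992 in znfx-1 and 1.30e-21 to 0.915 in wago-4). The difference between mutant and WT itself differed between F1 and P0, by -3.89 ± 0.61 for znfx-1 (SE, limma-voom, adjusted p = 1.83e-05) and by -2.70 ± 0.56 for wago-4 (SE, adjusted p = 0.0147). The wago-4 call held in 11 of 26 alternatives, with adjusted p from 1.87e-13 to 0.9999. It was lost without each of 8 libraries (WT P0 replicate 2, wago-4 P0 replicate 1 and the 6 F1 libraries), where the value lay between -2.84 and -2.23. The unadjusted limma-voom p of this difference was 6.33e-06 and at most 0.00252 in the 26 alternatives; oma-1 was chosen before the data were examined. The znfx-1 call held in 21 of 26 alternatives (adjusted p 2.74e-21 to 0.9996) and was lost without znfx-1 F1 replicate 1, where the value was -4.57 (adjusted p = 0.211). It was also lost with totals of non-structural (-3.77), miRNA (-3.50) or 21U-RNA reads (-4.05) and on reads outside the block of P0 sense reads (-0.58), and that of wago-4 with these totals, median-ratio factors, limma-trend, all lengths (-3.07 to -2.66) and such reads (-3.42).

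Sense reads of oma-1, the strand of its mRNA, were found in P0 at 647 ± 56.3 RPM in WT, 750 ± 96.6 in znfx-1 and 564 ± 12.7 in wago-4 (SD, n = 2 each). In F1 there was 1 such read in WT F1 replicate 1. The other 5 F1 libraries had none, where a count of 0 allows 11.2 to 35.3 RPM. The P0 sense reads formed a block on chromosome IV from 8889500 to 8890649 (1150 nt), in the positions of the files, whose genome build is not given in the sources used here. This block held 3345 of the 3356 P0 sense reads counted around the gene, and it is called the trigger part. Antisense reads in the span of oma-1 and more than 100 nt outside this part numbered 87 in WT, 29 in znfx-1 and 49 in wago-4 in P0, and 35, 11 and 1 in F1. All 11 in znfx-1 F1 came from replicate 1. Relative to aligned reads, the means were 46.96 RPM in WT, 19.81 in znfx-1 and 29.01 in wago-4 in P0 (n = 2 each). In F1 they were 64.63, 20.48 and 1.92 RPM. Both znfx-1 P0 libraries (15.85 and 23.77 RPM) thus lay below both WT P0 libraries (43.05 and 50.87 RPM). The P0 difference of znfx-1 from WT on reads outside the trigger part was -1.10 on the log2 scale and did not pass. On these reads alone the F1 difference of znfx-1 from WT was -1.68 on the log2 scale and did not pass (limma-voom, adjusted p = 0.0954; range over all alternatives 7.70e-22 to 0.0954). In wago-4 the F1 difference on these reads was -3.86 and passed (limma-voom, adjusted p = 0.0022; range over all alternatives 9.69e-27 to 0.0149). The P0 to F1 change in znfx-1 was then 0.03 (limma-voom, adjusted p = 0.992; range 2.03e-30 to 0.992). Of the oma-1 antisense reads, 53.5% in F1 and 35.8% in P0 were 22 nt long, over all genotypes. The paralog oma-2 had 0 to 14 antisense reads per library and did not enter the tests, and nothing shows where the alignment placed reads that match both genes.

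**Figure D2:**
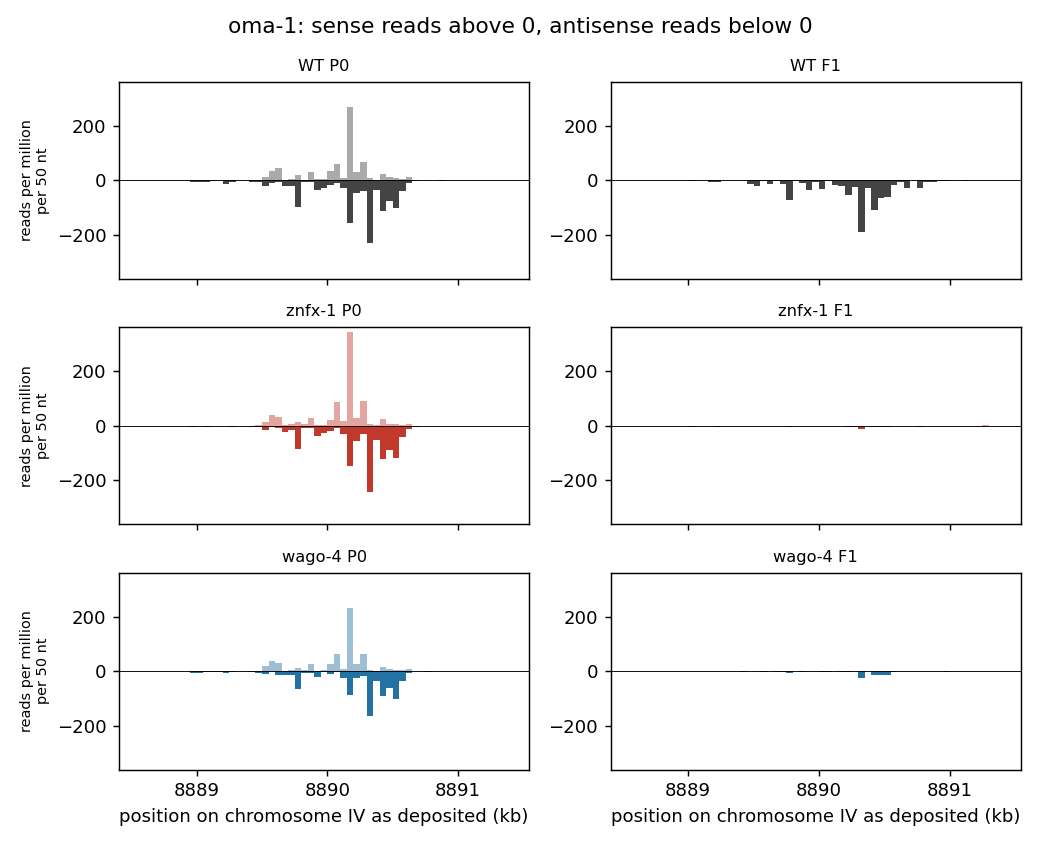
Sense reads (above 0, pale) and antisense reads (below 0, dark) of 20 to 24 nt in RPM in bins of 50 nt along oma-1 (position on chromosome IV in kb, as the files give it), as means of 2 libraries per group. P0 groups are on the left and F1 groups on the right on the same axes; sense reads lie between 8889500 and 8890649 in P0, and F1 antisense reads are seen mainly in WT.

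Across the 2319 genes tested, more genes had lower than higher antisense siRNAs in znfx-1 mutants. Over both generations 562 genes changed, of which 449 fell and 113 rose (limma-voom, adjusted p under 0.05). The number of rises was less stable than that of falls: it was 10 to 24 with the 3 read totals, 31 with limma-trend and 50 without a filter. It was 34, 37, 41, 67, 70 and 73 without WT P0 replicate 2, znfx-1 F1 replicate 1, WT F1 replicate 1, znfx-1 F1 replicate 2, WT F1 replicate 2 and znfx-1 P0 replicate 1. The median log2 fold changes of the 449 and 113 genes were -2.06 and 1.38, and 534 changed at least 2-fold. Among the named genes, hpo-39 and prx-11, a peroxisomal factor, had no reads in the 4 znfx-1 libraries against 332 and 133 in WT. They were at least 75.8-fold and at least 30.4-fold lower, with a floor of 3 reads over the group. The calponin gene cpn-4 fell from 1163 ± 338 to 18.0 ± 23.8 CPM, the collagen gene col-111 from 1094 ± 305 to 16.8 ± 23.7 and rpi-2 from 1672 ± 316 to 33.4 ± 22.7 (SD, n = 4). The zinc-finger gene znf-782 fell from 1718 ± 367 to 45.7 ± 35.6 CPM, zig-5 from 1139 ± 394 to 96.1 ± 93.3 and aex-6, a Rab GTPase gene, from 1899 ± 723 to 110 ± 32.2 (SD, n = 4). The nudix gene ndx-2 and neto-1 kept 3 reads each in znfx-1. They were 42.0-fold lower (exact 95% counting interval 14.2 to 206) and 43.9-fold lower (14.8 to 215). The adjusted p of these 10 genes in limma-voom ran from 2.33e-15 (rpi-2 and znf-782) to 1.04e-09 (neto-1).

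Rises in znfx-1 were smaller. The gene har-2 rose from 41.3 ± 33.9 to 302.5 ± 156 CPM (SD, n = 4), a log2 fold change of 2.59 ± 0.51 (SE, limma-voom, adjusted p = 2.04e-05). The poly(ADP-ribose) polymerase gene tank-1 rose from 60.5 ± 40.6 to 298 ± 88.0 CPM and the stress sensor kinase gene ire-1 from 78.7 ± 42.0 to 294 ± 139 (SD, n = 4). On the log2 scale mttu-1 rose by 1.88, alkb-8 by 1.86, rnf-121 by 1.81 and the chromatin remodeller gene chd-1 by 1.67. The sphingolipid gene sptl-1 and unc-16 both rose by 1.60, and rbc-1 rose by 1.55. The adjusted p of the 10 rises in limma-voom was at most 0.00979 (sptl-1). With miRNA totals as the scaling 8 of them, all but har-2 and tank-1, no longer passed, with values of 1.2 (rbc-1) to 1.78 (rnf-121). Totals of non-structural and of 21U-RNA reads both ended the calls of chd-1, mttu-1, rbc-1, sptl-1 and unc-16 (1.37 to 1.79). Without a filter beyond 1 read these 5 and alkb-8 did not pass (1.2 in rbc-1 to 1.54 in alkb-8). Limma-trend ended the calls of chd-1 (1.65), mttu-1 (1.61) and sptl-1 (1.39), reads of all lengths those of chd-1 and rnf-121 (1.29), and reads of 22 nt that of rbc-1 (1.17). Calls were also lost without znfx-1 F1 replicate 1 (alkb-8 1.55, ire-1 1.56, mttu-1 1.76, rnf-121 1.82, chd-1 1.58, unc-16 1.63, rbc-1 1.35), WT P0 replicate 2 (chd-1 1.41, unc-16 1.37, rbc-1 1.22, sptl-1 1.31), WT F1 replicate 1 (rnf-121 1.62, rbc-1 1.49, sptl-1 1.08) or WT F1 replicate 2 (chd-1 1.17, unc-16 1.24). These 20 genes were taken by a fixed rule from 378 falls and 63 rises that met its conditions.

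Among the gene lists, all 5 collagen genes tested fell in znfx-1, with log2 fold changes of -5.17 (col-111), -3.03 (col-71), -2.86 (col-157), -2.53 (col-155) and -1.63 (col-45), and 5 passed adjusted over the list alone. The last 3 were named after their values were seen. The list stood apart from the other genes in limma's camera test (adjusted p = 1.74e-04), but not with its own correlation (adjusted p = 0.503 with an estimated correlation). Of 45 BATH, MATH and F-box family genes, 18 fell and 1 rose (21 changed adjusted over the list alone). Among them fbxa-61 fell by 2.74 and fbxa-218 by 2.65, and bath-40 rose 2.07-fold. Camera gave an adjusted p of 0.0115 (adjusted p = 0.630 with an estimated correlation). All 3 chemoreceptor family genes tested fell (3 adjusted over the list alone, camera adjusted p = 0.118), among them sra-35 at -1.89 and srt-43 at -1.73. The neuropeptide genes flp-16 (-3.16) and nlp-81 (-2.54) fell among 3 neuron genes (2 adjusted over the list alone, camera adjusted p = 0.118). The sperm genes spe-41 (-1.90) and spe-47 (-1.61) fell among 3 tested (2 adjusted over the list alone, camera adjusted p = 0.259). Without znfx-1 F1 replicate 1 the calls of sra-35 (-1.97), srt-43 (-1.74), spe-41 (-1.88) and bath-40 (0.69) were lost, that of spe-41 also without WT F1 replicate 1 (-1.44), and that of bath-40 without 9 others, so that it passed in 7 of 24 alternatives. With totals of non-structural reads the fall of spe-41 (-1.89) did not pass.

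Of 7 loci of WAGO or piRNA-directed siRNAs, eri-6 fell by 2.30 and bath-45 by 1.78 among 3 falls, and sid-1, a dsRNA transporter gene, rose by 0.84 (4 adjusted over the list alone, camera adjusted p = 0.118). Of 34 small RNA pathway genes eri-6 and znfx-1 fell and sid-1 rose (3 adjusted over the list alone, camera adjusted p = 0.274). Of 14 germ granule genes meg-3 rose by 2.45 and glh-1 fell by 0.86 (1 adjusted over the list alone, camera adjusted p = 0.338). Of 13 chromatin regulators met-1 rose by 1.30 (1 adjusted over the list alone, camera adjusted p = 0.189). Of 6 ribosomal protein genes rpl-11.1 and rpl-41.2 both rose by 1.40 (2 adjusted over the list alone, camera adjusted p = 0.138). Of 28 oogenesis and maternal genes rec-8 rose by 0.94 (0 adjusted over the list alone, camera adjusted p = 0.118). Of 6 histone genes his-24 fell by 1.32 (2 adjusted over the list alone, camera adjusted p = 0.634). Of 8 nuclear hormone receptor genes nhr-15 fell by 3.30 and nhr-229 by 0.92 (3 adjusted over the list alone). The receptor list had a median of 0.20, a mean of -0.30 and a downward camera test (adjusted p = 0.666), and its median was -0.077 with totals of non-structural reads and -0.28 with miRNA totals. None of 13 ERGO-1 targets (camera adjusted p = 0.634), 3 C-type lectin genes (camera adjusted p = 0.336) or the 1 muscle gene tested passed, over all genes or adjusted over the list alone. No intestine gene was deep enough to test. The rises of rec-8, sid-1, rpl-11.1, rpl-41.2 and met-1 were lost with totals of non-structural, miRNA or 21U-RNA reads as the scaling and without WT F1 replicate 1, where they were 0.56, 0.85, 1.33, 0.88 and 0.64. Without a filter beyond 1 read none of these 5 passed either (0.52 in sid-1 to 1.18 in rpl-41.2). They passed in 4 of 24, 12 of 25, 14 of 24, 12 of 24 and 17 of 25 alternatives. The rise of rec-8 was lost without each library but wago-4 P0 replicate 2 (0.56 to 1.03), and that of sid-1 without WT P0 replicate 2, znfx-1 P0 replicate 1 and each F1 library (0.67 to 0.85). Those of rpl-11.1 and rpl-41.2 were lost without either znfx-1 F1 library, that of rpl-11.1 also without WT P0 replicate 1 or znfx-1 P0 replicate 2 (0.97 to 1.54). That of rpl-41.2 was lost without WT P0 replicate 2, znfx-1 P0 replicate 1 or WT F1 replicate 2 too (0.88 to 1.69), and that of met-1 without znfx-1 F1 replicate 2 (1.0). The calls of glh-1 and nhr-229 were lost without WT F1 replicate 2 (-0.89 and -0.85), that of glh-1 also without znfx-1 P0 replicate 2 (-0.92) or znfx-1 F1 replicate 1 (-1.35), and that of nhr-229 without WT P0 replicate 1 (-0.75). Totals of non-structural, miRNA or 21U-RNA reads ended the calls of glh-1 (-1.06, -1.26 and -0.98) and nhr-229 (-1.07, -1.25 and -1.02), and meg-3 did not pass with miRNA totals or with limma-trend (1.34). These 3 passed in 18, 19 and 20 of 25, 25 and 22 alternatives.

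The excess of falls in znfx-1 was present in each generation: 394 of 455 changed genes were lower in P0 and 267 of 289 in F1 (limma-voom). Of the 455 genes called in P0, 262 were called in F1, all in the same direction, and 453 had the same sign there. Only oma-1 passed the limma-voom test that the znfx-1 difference itself differed between F1 and P0 (1 gene, with 53 at an unadjusted p under 0.05). Scaling moved the balance of rises and falls. Totals of non-structural, miRNA or 21U-RNA reads hold reads of every length, so they also carry differences in read length between libraries. Over both generations 79.9% of called genes were lower with TMM factors, 85.1% with median-ratio factors, 95.2% with totals of non-structural reads, 97.4% with miRNA totals and 93.5% with 21U-RNA totals. In P0 the share went from 86.6% to 98.3% with miRNA totals. Totals of non-structural, miRNA and 21U-RNA reads left 99, 78 and 124 changed genes in F1 (98, 77 and 123 lower), and 21U-RNA totals 262 in P0 (253 lower). The median over all genes was 0.15 with TMM factors and -0.21 with miRNA totals, so rises and falls hold relative to that shift. The F1 count dropped from 289 to 16 without znfx-1 F1 replicate 1, and the P0 count was 227 without znfx-1 P0 replicate 2 and 233 with limma-trend.

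In wago-4 mutants 267 genes changed over both generations, 176 up and 91 down with TMM factors (limma-voom, adjusted p under 0.05). Without WT P0 replicate 2 the balance turned, with 98 up and 111 down. Their median log2 fold changes were 1.52 and -1.97, and 246 changed at least 2-fold. The thiamine kinase gene tpk-1 rose from 41.9 ± 10.5 to 738 ± 206 CPM and the tensin gene tns-1 from 166 ± 94.6 to 2194 ± 587 (SD, n = 4). The astacin protease gene nas-36 rose from 137 ± 109 to 1289 ± 511 CPM and the G protein gene gpa-1 from 35.7 ± 42.4 to 491 ± 357 (SD, n = 4). From low WT levels idpp-2 rose by 3.59, pigx-1 by 3.56 and atgp-1 by 3.14 on the log2 scale. Over the 4 WT libraries ltd-1 had 1 read, mig-21 had 2 and calm-1 had 2, against 153, 101 and 74 in wago-4. They were 211-fold (exact 95% counting interval 37.3 to 8379), 69.6-fold (18.8 to 582) and 51.0-fold (13.6 to 429) higher. The adjusted p of these 10 rises in limma-voom ran from 6.11e-13 (tns-1) to 4.91e-06 (idpp-2).

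Among the falls in wago-4, the ciliary kinesin gene osm-3 went from 3008 ± 722 to 355 ± 208 CPM and hpo-39 from 908 ± 155 to 136 ± 83.1 (SD, n = 4). The cadherin gene cdh-12 went from 822 ± 206 to 179 ± 117 CPM and ndx-2 from 456 ± 168 to 52.4 ± 15.1 (SD, n = 4). The F-box gene fbxa-150 fell by 3.18, the serotonin transporter gene mod-5 by 2.98 and the TGF-beta ligand gene daf-7 by 2.93 on the log2 scale. Over the 4 wago-4 libraries cdk-14 kept 1 read, pdfr-1 kept 3 and math-44 kept 3, against 93, 84 and 67 in WT. They were 67.5-fold (exact 95% counting interval 11.8 to 2695), 20.3-fold (6.72 to 101) and 16.2-fold (5.31 to 80.6) lower. The adjusted p of these 10 falls in limma-voom ran from 1.71e-13 (osm-3) to 4.52e-04 (math-44). These 20 genes were taken by the same rule from 146 rises and 77 falls.

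No gene list stood apart in wago-4 by camera: 0 of the 15 lists with at least 3 tested genes passed, and 1 had an unadjusted p under 0.05. The lowest adjusted p in limma's camera test was 0.274 (germ granule genes), and the directional test of limma's fry gave 0 lists, with a lowest adjusted p of 0.414. The mixed test of fry, which asks for changes in either direction and does not compare a list with other genes, passed 4 lists. These were the BATH, MATH and F-box genes (adjusted p = 2.48e-07), the WAGO or piRNA-directed loci (3.48e-05), the small RNA pathway genes (2.75e-04) and the germ granule genes (0.023), against 8 lists in znfx-1. Of 14 germ granule genes meg-4 fell by 2.29 (1 adjusted over the list alone). Of 45 BATH, MATH and F-box family genes 7 fell and 5 rose (13 adjusted over the list alone), among them bath-1 at 2.38 and bath-24 at 1.55. That list had a median of 0.17, a mean of -0.11 and an upward camera test (adjusted p = 0.954). With totals of non-structural, miRNA and 21U-RNA reads its camera test pointed down, its medians were -0.018, -0.24 and 0.013, and 1, 1 and 2 genes rose against 5, 6 and 4 that fell. Of 34 small RNA pathway genes rde-11 rose by 1.26 and sid-1 by 1.12 among 3 rises, and rrf-2 fell by 1.07 (4 adjusted over the list alone). This list had a median of -0.10, a mean of 0.01 and a downward camera test (adjusted p = 0.954), and with these 3 totals 0 of its genes passed. Of 7 loci of WAGO or piRNA-directed siRNAs sosi-1 fell by 2.22 while rde-11 and sid-1 rose (3 adjusted over the list alone, camera adjusted p = 0.775). Single members of other lists passed: spe-47 fell by 1.36 among 3 sperm genes, his-24 rose by 0.83 among 6 histone genes, flp-16 rose by 1.17 among 3 neuron genes and clec-90 rose by 1.58 among 3 C-type lectin genes. Adjusted over the list alone 1 sperm, 1 histone, 2 neuron and 1 lectin gene passed. The lectin list had a median of -0.39, a mean of 0.08 and an upward camera test. None of the 28 oogenesis and maternal genes, 13 ERGO-1 targets, 13 chromatin regulators, 6 ribosomal protein genes, 8 nuclear hormone receptor genes, 3 chemoreceptor family genes, 5 collagen genes or the 1 muscle gene passed over all genes. Adjusted over the list alone 1 ribosomal protein gene, 1 chemoreceptor gene and the muscle gene did. Without WT F1 replicate 1 the calls of flp-16 (0.98), his-24 (0.83), rrf-2 (-0.99), spe-47 (-1.52) and clec-90 (1.67) were lost, and without wago-4 F1 replicate 1 those of flp-16 (1.24), his-24 (0.83), rrf-2 (-0.90) and spe-47 (-0.86). Calls were also lost without WT P0 replicate 1 (rrf-2 -0.89, spe-47 -1.13), WT P0 replicate 2 (flp-16 0.74, his-24 0.56), wago-4 P0 replicate 1 (flp-16 0.99, his-24 0.70, spe-47 -1.21), wago-4 P0 replicate 2 (rrf-2 -0.92) or wago-4 F1 replicate 2 (flp-16 1.13, his-24 0.82, rrf-2 -1.14, spe-47 -1.65). That of his-24 was lost without WT F1 replicate 2 or either znfx-1 F1 library as well (0.76 to 0.81). Totals of non-structural, miRNA or 21U-RNA reads each ended the calls of sid-1 (0.67 to 0.96), rde-11 (0.81 to 1.11), rrf-2 (-1.45 to -1.18), spe-47 (-1.73 to -1.44), his-24 (0.40 to 0.69), flp-16 (0.70 to 0.98) and clec-90 (1.19 to 1.45). Without a filter beyond 1 read flp-16 (1.21), rrf-2 (-0.98) and spe-47 (-1.24) did not pass, and with limma-trend flp-16 (1.04), his-24 (0.83), rrf-2 (-0.96) and spe-47 (-1.22) did not. Median-ratio factors ended the calls of his-24 (0.90) and rrf-2 (-1.01). The call of bath-24 was lost with the first 2 of these (1.36 and 1.13) and that of meg-4 with limma-trend (-2.12).

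In P0 207 genes changed in wago-4 (145 up, 62 down) and in F1 84 did (51 up, 33 down) by limma-voom. Of these, 72 were called in both generations, all in the same direction, and 205 of the 207 had the same sign in F1. Only oma-1 passed the limma-voom test that the wago-4 difference differed between F1 and P0 (1 gene, with 51 at an unadjusted p under 0.05). The excess of rises depended on the scaling and on single libraries. Over both generations 34.1% of called genes were lower with TMM factors, 31.5% with median-ratio factors, 51.8% with totals of non-structural reads, 62.6% with miRNA totals and 50% with 21U-RNA totals. The 176 rises became 53, 40 and 56 with these 3 totals, and the 91 falls 57, 67 and 56. With miRNA totals the lower share went from 30% to 51.9% in P0 and from 39.3% to 82.4% in F1. The median over all genes moved from -0.05 to -0.49 with them. Counts over both generations were 130 with limma-trend, 158 without WT F1 replicate 1 (91 up, 67 down), 209 without WT P0 replicate 2 (98 up, 111 down) and 187 without wago-4 F1 replicate 1 (127 up, 60 down). In P0 they were 41 with limma-trend (23 up, 18 down), 120 without WT P0 replicate 2 (40 up, 80 down), 108 without wago-4 P0 replicate 1 (60 up, 48 down), 192 without WT P0 replicate 1 (154 up, 38 down) and 245 without wago-4 P0 replicate 2 (211 up, 34 down). In F1 they were 29 without WT F1 replicate 1 (11 up, 18 down), 50 without WT F1 replicate 2 (32 up, 18 down), 34 without wago-4 F1 replicate 1 (29 up, 5 down) and 43 without wago-4 F1 replicate 2 (29 up, 14 down).

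Compared with each other over both generations, the mutants differed at 699 of 2319 genes, of which 503 were lower and 196 higher in znfx-1 (limma-voom). The number higher was 86 to 118 with other scalings, 113 with limma-trend and 129 with all lengths. It was 107 to 122 without wago-4 P0 replicate 1, znfx-1 F1 replicate 1, wago-4 F1 replicate 1 or wago-4 F1 replicate 2. Of the 562 genes changed in znfx-1 and the 267 changed in wago-4 against WT, 124 were called in both. Among these 53 fell in both, 9 rose in both and 62 went in opposite directions. Lists of these sizes drawn independently would share 17.6, 8.6 and 38.5. With unchanged groups simulated against the same WT libraries no gene was shared. Genes rarely pass where no group differs, so this cannot show whether the shared WT libraries raised the 53 and 9. Shared WT libraries alone push both fold changes the same way (simulated correlation 0.478), which argues against them as the source of the 62 opposite calls. With the WT libraries split between the comparisons by replicate number, 40 or 51 genes fell in both, 0 rose in both and 42 or 22 went in opposite directions. Lists drawn independently in these splits would share 13.3 or 16.6 falls and 1.5 or 0.5 rises, with 23.8 or 15.1 in opposite directions. Across genes, which are not independent replicates, the correlation of the fold changes was 0.005 (simulated from shared controls alone: 0.478) and their covariance 0.005 (simulated: 0.095). Among the named genes, osm-3 fell in both mutants (-3.67 in znfx-1 and -3.33 in wago-4), as did hpo-39, ndx-2, cdh-12 (-1.40 and -2.59) and mod-5 (-2.84 and -2.98). The neuropeptide gene flp-16 (-3.16 and 1.17) and the linker histone gene his-24 (-1.32 and 0.83) fell in znfx-1 and rose in wago-4, the rises passing in 15 and 10 of 25 alternatives.

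**Figure D3:**
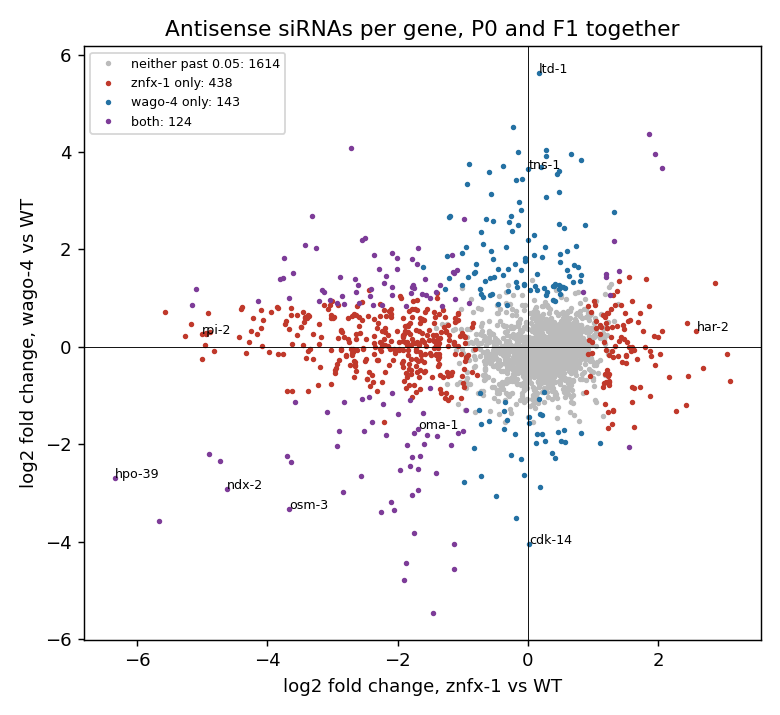
Fitted log2 fold change of antisense siRNAs in znfx-1 against WT (x axis) and in wago-4 against WT (y axis) for 2319 genes over both generations, coloured by which comparison passed an adjusted p of 0.05 in limma-voom. Of these, 438 genes passed in znfx-1 alone, 143 in wago-4 alone and 124 in both; fitted values of genes without reads in a group, such as hpo-39, depend on the offset of the method and are no bounds.

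Between generations, counts of changed genes depended on the processing. In WT 1 gene passed in limma-voom (153 at an unadjusted p under 0.05): Y57G11C.27 rose in F1 by 4.38 ± 0.69 on the log2 scale (SE). This call was lost without WT P0 replicate 2 (3.82, where 8 other genes, all lower in F1, passed), with totals of non-structural (4.21) or 21U-RNA reads (3.64) and with limma-trend (3.36). The gene also rose in wago-4 (4.55 ± 0.73, SE) and in znfx-1, with CPM of 0 to 32.2 in the 6 P0 libraries and 335 to 939 in the 6 F1 libraries. In znfx-1 8 genes passed, among them oma-1, W04B5.8 (-2.28 ± 0.41, SE), F55C9.3 (-2.26 ± 0.49, SE) and fbxb-100 (3.41 ± 0.78, SE). These 3 passed in 19 of 25, 16 of 25 and 14 of 24 alternatives. All 3 calls were lost without znfx-1 P0 replicate 1 (-1.75, -1.89 and 2.52), those of F55C9.3 and fbxb-100 without znfx-1 F1 replicate 1 (-1.69 and 2.34), that of W04B5.8 without znfx-1 F1 replicate 2 (-2.16) and that of fbxb-100 without wago-4 F1 replicate 2 (3.16). With miRNA totals as the scaling W04B5.8 (-0.94), F55C9.3 (-0.89) and fbxb-100 (4.75) did not pass, nor with totals of non-structural reads (-1.99, -1.87 and 3.74) or limma-trend (-2.33, -2.08 and 2.49). F55C9.3 and fbxb-100 did not pass with 21U-RNA totals (-2.68 and 2.90) or all lengths (-2.09 and 2.31). F55C9.3 also failed with median-ratio factors (-2.24) and only the groups compared (-2.40), W04B5.8 with the latter (-2.22), and fbxb-100 without a filter (3.07) and with 22 nt (2.85). In wago-4 2 passed, oma-1 and Y57G11C.27, the latter not with 21U-RNA totals (3.45), limma-trend (3.57) or only the groups compared (4.58). These counts were not stable: leaving out 1 library gave 1 to 8 in WT (8 without WT P0 replicate 2), 2 to 31 in znfx-1 (31 without znfx-1 P0 replicate 2) and 2 to 34 in wago-4 (34 without wago-4 P0 replicate 2). Reads of all lengths gave 51 in WT and 19 in wago-4, and a fit of only the groups compared gave 19 in WT, 1 in znfx-1 and 5 in wago-4. Blocks by replicate number within generation raised the counts further in every genotype, as given below with the other processing choices. Nothing in the labels says that these numbers mark a shared batch.

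Among other small RNA classes few single entries passed between genotypes. Of 97 miRNA entries mir-257 fell by 2.27 in znfx-1 (SE 0.36, limma-voom, adjusted p = 0.00199), as did 1 of 2 copies of mir-258.2, by 1.81 (SE 0.41, adjusted p = 0.0284), and none rose. The other copy had a similar value, -1.64 (SE 0.42, limma-voom, adjusted p = 0.0553), that did not pass. These entries were named after their values were seen, and how reads split between the near-identical copies of mir-258.2 is uncertain. The count of 2 entries was 1 without WT P0 replicate 2, znfx-1 P0 replicate 1 or any 1 of the 6 F1 libraries. In wago-4 limma-voom called 0 entries (3 at an unadjusted p under 0.05). Of the 11 tested entries that hold miRNA markers of stage and tissue, limma-voom called 0 in either mutant over all entries or adjusted over the list alone. Their log2 fold changes were -0.32 to 0.14 in znfx-1 and -0.54 to 0.12 in wago-4. Antisense reads of 26 nt were deep enough at 5 genes, of which C34G6.3, named after its value was seen, rose in znfx-1 by 1.32 (SE 0.37, limma-voom, adjusted p = 0.0293). This call was lost without each of the 12 libraries, and 0 of 5 passed in wago-4 (limma-voom, 1 at an unadjusted p under 0.05).

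The share of aligned reads taken by antisense siRNAs was 16.5% ± 7.61 in znfx-1, 19.7% ± 3.65 in wago-4 and 21.3% ± 5.37 in WT (SD, n = 4; exact two-sided permutation tests against WT, p = 0.343 and 0.686). The miRNA share was 39.1% ± 16.2, 38.4% ± 9.66 and 33.5% ± 10.3 (exact permutation p = 0.543 for each mutant). The 21U-RNA share was 1.18% ± 0.399, 1.21% ± 0.444 and 1.2% ± 0.316 (exact permutation p = 0.857 and 0.971). The share of structural RNA was 5.21% ± 0.919, 4.84% ± 1.63 and 5.00% ± 1.92 (exact permutation p = 0.829 and 0.8). Adjusted over the 10 tests of this kind the lowest p was 0.952, and 4 libraries against 4 can reach 0.0286. These tests pooled P0 and F1 without regard to generation, so differences between generations add to their spread and can hide a difference between genotypes. Within P0 alone the siRNA share was 16.7% ± 7.09 in znfx-1 and 23.1% ± 7.28 in WT, and within F1 16.4% ± 11 and 19.6% ± 4.63 (SD, n = 2), where no exact test can go below 0.333. The miRNA share in P0 alone was 52.6% ± 4.39 in znfx-1, 46.1% ± 5.34 in wago-4 and 42.0% ± 3.51 in WT, and in F1 alone 25.6% ± 6.49, 30.8% ± 4.34 and 24.9% ± 3.87 (SD, n = 2). These miRNA shares count reads of any length, many of which in F1 were not of 20 to 24 nt. At 20 to 24 nt the share was 15.0% and 13.5% in the WT F1 libraries. It was 23.1% and 4.59% in znfx-1 F1, 19.2% and 19.9% in wago-4 F1 and 37.8% to 52.3% in the P0 libraries. The relative position of antisense reads along transcripts could be measured at only 1 gene with 50 reads in every library. It differed from WT by 0.0449 in znfx-1 and 0.0046 in wago-4 (exact permutation p = 0.657 and 0.857). Over 46 genes with 50 reads in the 11 deeper libraries, a choice made after the data were seen, it differed by -0.0109 in znfx-1 and 0.0088 in wago-4 (exact permutation p = 0.286 and 0.0286, the latter the smallest possible).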

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

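The tests of read numbers, scaling, oma-2 and F1 feeding for oma-1, and those of P0 alone and of moved read places for the falls in znfx-1, were chosen after the results were seen.

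The difference of oma-1 siRNAs between mutant and WT was itself different in F1 and P0, for a gene chosen before the data were examined. It differed by -3.89 on the log2 scale for znfx-1 (limma-voom, adjusted p = 1.83e-05) and by -2.70 for wago-4 (adjusted p = 0.0147). The first call was lost without znfx-1 F1 replicate 1 (-4.57), with totals of non-structural, miRNA or 21U-RNA reads (-4.05 to -3.50) and outside the trigger part (-0.58). The second passed in 11 of 26 alternatives and was lost, among others, without each of WT P0 replicate 2, wago-4 P0 replicate 1 and the 6 F1 libraries (-2.84 to -2.23). As for the low F1 levels of oma-1 in both mutants, fewer reads were argued against, since at the lower WT share the 4 mutant F1 libraries would have held up to 171 oma-1 reads, and none had over 19.9% of its number. Over 4 other scalings the change nearest to 0 of both mutants was -2.97, so scaling did not give the pattern, whereas reads shared with oma-2 stay open: oma-2 reads came to 0.2% of the oma-1 reads in WT F1, but nothing shows where the alignment placed reads that match both genes. Feeding of WT alone in F1 was argued against, as oma-1 sense reads in WT F1 came to 0.26% of those in the lowest P0 group, whereas the genotype, the difference that the design names, stays open along with differences between cultures, which were not tested. On reads outside the trigger part alone the znfx-1 difference in F1 was -1.68 and did not pass (limma-voom, adjusted p = 0.0954, range over all alternatives 7.70e-22 to 0.0954). This rests on 35 reads in WT and 11 in znfx-1, whereas the F1 difference of wago-4 (-3.86, 1 read) passed. On such reads the znfx-1 difference in P0 was -1.10 and did not pass, so it was below 0 in both generations.

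In znfx-1, 449 of 562 changed genes had fewer antisense siRNAs. The choice of scaling was argued against as the source, since the lowest share of falls over 4 other scalings was 85.1%, although the count of rises moved with it. Shallow F1 libraries do not explain it either, as the share in P0 alone was 86.6%, nor does the different genome build, as moved read places gave 85.1%. The balance covers the tested genes only. They held 69.3% to 74.7% of antisense siRNAs in the znfx-1 libraries and 79.7% to 84.6% in the WT libraries. The znfx-1 genotype, the difference that the design names, stays open, as do second-site differences between the strains, and neither these nor a mechanism was tested.

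Splits of the 8 libraries of 2 genotypes into 4 and 4, with generation as a term, were compared with the real split by limma-voom, and 34 of 35 could be fitted. For znfx-1 against WT 1 of 34, the real one, gave as many as its 609 genes (highest other 138). The same held for wago-4 against WT with 1 of 34 (303 genes, highest other 27) and for znfx-1 against wago-4 with 1 of 34 (792 genes, highest other 338). For miRNA entries in znfx-1 it was 1 of 34 as well (3 entries, highest other 2), a small margin. A share of 1 of 34 is the lowest that these splits allow, but it is no p-value. Only splits balanced within each generation can stand in for the real one, and these are fewer than 34. Every other split also leaves the genotype difference in its residual spread, which by itself lowers its count. These splits therefore cannot exclude chance. They cannot tell genotype from other differences that go with it. Where the real split gave 0, every split gives as many, so the count decides nothing: this was so for miRNA entries in wago-4 with 34 of 34 (6 at an unadjusted p under 0.05, highest other 8). For antisense reads of 26 nt it was 34 of 34 in znfx-1 (1 at an unadjusted p under 0.05, highest other 4) and 34 of 34 in wago-4 (0 unadjusted, highest other 3).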

How the results depend on the processing

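Chosen after the data were seen were reads of 22 nt, moved read places, the doubled file as deposited, the block and left-out libraries for 26-nt reads and miRNA entries, antisense library sizes for 26-nt reads, the 46 genes of the position measure, the split with WT replicate 2 for znfx-1, and the miRNA comparisons between generations. The other alternatives were fixed before. The fall of oma-1 in wago-4 against WT in F1 passed in all 26 alternatives (-3.86 to -2.82), and that in znfx-1 in 25 (-4.43 to -3.40), the exception being reads outside the trigger. The count of changed genes in znfx-1 over both generations (562) was 372 to 693 and that between the mutants (699) was 451 to 876. Of the named gene values, 924 in znfx-1 and 746 in wago-4 stayed as they were in direction and side of the threshold, 146 and 60 lost the call, 1 in wago-4 gained it and 1 in znfx-1 changed sign. Of the other values apart from left-out libraries 248 were unchanged by the same measure, 72 counts or values moved, 16 lost a call, 14 changed sign and 1 gained a call. With 1 library left out these numbers were 325, 59, 9, 23 and 0. Depth limits F1: 4-fold changes in znfx-1 were found at 25% of simulated genes there and at 74% in P0. Not run were reads of 22 nt or 26 nt with a 5′ G, for which no genome sequence was used, all listed alignments, since each read is listed at 1 place, and the position measure at 200 reads, which no gene reached. Unless stated, the cause was not tested.

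Many counts were lower with totals in place of TMM factors. These totals hold reads of every length, whereas the counts they scale are of 20 to 24 nt. Reads under 18 nt made up 9.38% of WT P0 replicate 2 and 70.2% of znfx-1 F1 replicate 2, so these scalings also carry differences in read length. With totals of non-structural reads the counts of changed genes were 99 in znfx-1 F1 (289 with TMM), and for wago-4 110 over both generations (267), 66 in P0 (207) and 27 in F1 (84). Between generations they were 0 in WT (1), 2 in znfx-1 (8) and 1 in wago-4 (2). Totals of miRNA reads gave 78 in znfx-1 F1, 107, 54 and 17 in wago-4, 451 between the mutants, and 1 in znfx-1 and 1 in wago-4 between generations. Totals of 21U-RNA reads gave 372, 262 and 124 in znfx-1 (562, 455 and 289), 112, 72 and 33 in wago-4, and 0, 3 and 1 between generations. Median-ratio factors gave 4 in znfx-1 between generations. The 2 counts of 0 in WT came with 44 and 177 genes at an unadjusted p under 0.05 in limma-voom. With limma-trend the counts were 233 in znfx-1 P0, 130, 41 and 52 in wago-4, and 0 (68 unadjusted), 2 and 1 between generations. Without a filter they were 44 in wago-4 F1, and 4 in WT and 7 in wago-4 between generations, where more genes were tested. Reads of all lengths gave 47 in wago-4 F1, and 51 in WT and 19 in wago-4 between generations. Reads of 22 nt gave 164, 121 and 54 in wago-4, with fewer reads. Only the groups compared gave 19, 1 and 5 between generations. Moved places gave 2 in WT and 4 in wago-4 between generations, and the doubled file 7 in WT.

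The 1 gene, oma-1, whose mutant difference differed between F1 and P0 was no longer called for znfx-1 with totals of non-structural (-3.77), miRNA (-3.50) or 21U-RNA reads (-4.05), which left 0 genes (24 to 35 at an unadjusted p under 0.05 in limma-voom). For wago-4 it was not called with these totals (-2.66, -2.87 and -3.07), median-ratio factors (-2.71), limma-trend (-2.70) or all lengths (-2.96), with 0 genes (8 to 68 unadjusted). The fall of oma-1 from P0 to F1 lost its call with miRNA totals in znfx-1 (-3.12) and wago-4 (-2.49) and with non-structural totals in wago-4 (-3.04). The sign of oma-1 in znfx-1 P0, not called, became negative with miRNA totals (-0.33) and without a filter (-0.064), and that of WT between generations positive with miRNA totals (0.38) and 22 nt (0.28). Reads outside the trigger part, which are few, gave -1.10 in znfx-1 P0, -1.68 in znfx-1 F1, 0.61, 0.026 and -2.81 between generations in WT, znfx-1 and wago-4, and -0.58 and -3.42 for the differences between generations. None of these 7 was called. Among single genes the value of wago-4 in znfx-1 was 0.36 with 22 nt.

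Nothing in the labels says that replicate numbers mark a shared batch, and 2 numbers are too few for correlations to decide. Deviations of libraries with the same number correlated by 0.368 to 0.499 within P0, by 0.068 to 0.098 within F1 and by -0.187 to -0.068 between generations, so that within a generation every library correlated best with its own number and between generations none did. With the replicate block the counts between generations were 3 in WT, 17 in znfx-1 and 8 in wago-4, and those of 26-nt genes 3 in znfx-1 and 1 in wago-4. With the block within generation they were 432, 403 and 166 in wago-4 and 179, 106 and 240 between generations, and the fall of wago-4 in its own mutant passed (-0.48). Genes that rose in znfx-1 then numbered 193, 176 and 51 over both generations, in P0 and in F1 (113, 61 and 22 without it), and those higher in znfx-1 than in wago-4 328 (196). The block moved no other total of changed genes by over 1.5 times.

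Leaving out 1 library assumes that a lone library varies like the other groups. In znfx-1 the counts were 227 to 503 in P0 (227 without znfx-1 P0 replicate 2), 16 to 313 in F1 (16 without znfx-1 F1 replicate 1), and 0 to 1 for the difference between generations (0, with 91 unadjusted, without the latter). In wago-4 they were 158 to 310 over both generations (158 without WT F1 replicate 1) and 108 to 245 in P0 (108 without wago-4 P0 replicate 1, 120 without WT P0 replicate 2). In F1 they were 29 to 89, with 29 and 50 without WT F1 replicates 1 and 2 and 34 and 43 without wago-4 F1 replicates 1 and 2. The difference between generations gave 0 to 1, with 0 (37 to 93 unadjusted) without WT P0 replicate 2, wago-4 P0 replicate 1 or any 1 F1 library. For oma-1 that difference was -4.57 to -3.45 in znfx-1 and -3.04 to -2.23 in wago-4. In P0 oma-1 was -0.27 to 0.64 in znfx-1 (below 0 without WT P0 replicate 2, -0.27, or znfx-1 P0 replicate 1, -0.26) and -0.82 to 0.024 in wago-4 (0.024 without WT P0 replicate 1).

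Between generations the counts with 1 library left out were 1 to 8 in WT, 2 to 31 in znfx-1 and 2 to 34 in wago-4. In WT they were 8 without WT P0 replicate 2, 6 and 5 without znfx-1 P0 replicates 1 and 2, 2 and 5 without wago-4 P0 replicates 1 and 2, and 3 without WT F1 replicate 2 or znfx-1 F1 replicate 1. In znfx-1 they were 14 without WT P0 replicate 2, 2 and 31 without znfx-1 P0 replicates 1 and 2, 4 without znfx-1 F1 replicate 2 and 5 without wago-4 F1 replicate 2. In wago-4 they were 4 and 5 without WT P0 replicates 1 and 2 and 34 without wago-4 P0 replicate 2.

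Other measures changed as follows. The 26-nt count of 1 in znfx-1 was 0 with antisense library sizes (0 unadjusted) and 0 to 0 without each library (0 to 1 unadjusted), and the miRNA count of 2 was 1 to 2. The gene list count of 2 in znfx-1 was 0 of 15 with an estimated correlation (1 unadjusted), against 5 by the directional test of fry. Genes changed alike in both mutants (62) were 40 with WT replicate 1 for znfx-1. The differences in percentage points were 0.0848 for the 21U-RNA share of znfx-1 in F1 alone, -0.0496 and -0.149 for that of wago-4 with 21-nt reads and in P0 alone, and 0.211 for the structural share of wago-4 in F1 alone. Without 1 library these shares were -0.181 to 0.128 (znfx-1) and -0.143 to 0.163 (wago-4) for 21U-RNA, -0.249 to 1.14 and -0.955 to 0.762 for structural RNA, and -3.26 to 0.703 for siRNAs in wago-4. None of these differences passed. The position difference of wago-4 was -0.0008 at 20 reads and -0.0078 in P0 alone, and over 46 genes in the 11 deeper libraries it was 0.0088 (exact permutation p = 0.0286, the smallest possible), with -0.0109 in znfx-1 (p = 0.286). Without 1 library it was -0.0053 to 0.0692 in znfx-1 and -0.0164 to 0.0223 in wago-4. The miRNA counts between generations were 17, 25 and 18 in WT, znfx-1 and wago-4 with totals of non-structural reads. Without 1 library they were 20 to 48, 22 to 43 and 18 to 53, among them 23, 22 and 20 in WT without WT P0 replicate 2, WT F1 replicate 1 and WT F1 replicate 2. The others that moved were 22 in znfx-1 without znfx-1 P0 replicate 2, and 23 and 18 in wago-4 without wago-4 P0 replicate 1 and wago-4 F1 replicate 2.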

Other observations

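The comparison of miRNA entries between generations was chosen after their values were seen.

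Many miRNA entries differed between F1 and P0 in all 3 genotypes. By limma-voom 37 of 97 entries changed in WT (17 higher and 20 lower in F1), 40 in znfx-1 (15 and 25) and 38 in wago-4 (23 and 15). Of these, 12 were higher and 12 lower in F1 in all 3 genotypes with TMM factors. Among the falls were those of mir-79 (-6.08 on the log2 scale in WT, -6.48 in znfx-1 and -5.79 in wago-4), mir-83 (-4.24, -4.52 and -4.05) and mir-60 (-3.94, -3.07 and -3.29). Among the rises were mir-359 (3.51, 3.16 and 4.35), mir-85 (2.79, 3.46 and 3.55) and mir-71 (2.68, 2.19 and 2.91). Also higher in F1 was let-7, by 2.22, 2.19 and 2.90, as were mir-48 by 1.99, 2.46 and 2.06, and lin-4 by 1.16, 0.88 and 1.77. The entry mir-241 rose in all 3 (2.22 in WT and 2.19 in wago-4), and mir-84 rose in WT (0.97) and wago-4 (1.44) and had a value of 0.72 in znfx-1 that did not pass. With totals of non-structural reads as the scaling, 17, 25 and 18 entries changed. Only 6 were then higher in znfx-1 and 7 lower in wago-4, so fewer than 12 were shared by all 3 genotypes in each direction. With these totals lin-4 (1.10, 0.18 and 1.69) and mir-84 (0.90, -0.011 and 1.34) did not pass in any genotype, and let-7 (1.49) and mir-71 (1.49) did not in znfx-1. The counts were 20 in WT without WT F1 replicate 2, 22 without WT F1 replicate 1 and 23 without WT P0 replicate 2, 22 in znfx-1 without znfx-1 P0 replicate 2, and 23 and 18 in wago-4 without wago-4 P0 replicate 1 and wago-4 F1 replicate 2. Reads under 18 nt made up 9.38% to 20.2% of each P0 library and 30.5% to 70.2% of each F1 library, and reads of 22 nt 46.4% to 51.3% and 8.37% to 30.2%. Every F1 library carried another 5′ linker barcode than every P0 library, so generation, barcode and any difference in stage at harvest cannot be told apart.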
